A study of Rattus norvegicus with 47 samples.

How the data were processed

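Total RNA, extracted with Trizol per the labels, from rat cortex and hippocampus was hybridised to 47 oligonucleotide arrays with 8799 probe sets each. The deposited values are an intensity per probe set (signal) on a linear scale. The summary algorithm and the scaling target of the authors are not given in the sources used here. The arrays' 2%-trimmed means lay between 2503 and 2504, within the tolerance of 5% set for counting the table as already scaled, so the values were kept as deposited. Signals ran from 0.313 to 206640. Values under the 25th percentile of all values (a signal of 185.8) were raised to it and log2 was taken. A fold against a group with arrays at this floor is therefore smaller than in the unfloored signal. Probe sets above the floor on at least 7 arrays, the size of the smallest group, were tested, without the 59 control probe sets, which left 7503. The number of arrays limits the precision.

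Gene symbols came from the platform's annotation, updated through gene identifiers: 7018 probe sets name 1 gene, 308 several and 1473 none, and 6104 of the 6122 tested probe sets with 1 symbol matched the reference by gene ID. The annotation is older than the reference. The tested probe sets cover 4242 genes. Groups were taken from the labels: side, region and hours after injury. Array 23 is labelled contralateral hippocampus although its number breaks the run of numbers of that side; it was kept as labelled. The labels name no treatment that differs within these groups, and sample numbers occur once each in the series, so no pairing or block was used.

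Tests used R 4.3.3, the package limma (3.58.1) and the package data.table (1.17.8). All 47 arrays went into 1 linear model of 6 group means per probe set, with moderated tests (eBayes with an intensity trend), all two-sided, and Benjamini-Hochberg adjustment over the 7503 probe sets within each of 8 comparisons at a threshold of 0.05. The comparisons were the side difference in cortex at 4 h, in cortex at 24 h and in hippocampus at 4 h, the time difference in ipsilateral and in contralateral cortex, the change of the cortical side difference with time, its difference from the hippocampal one at 4 h, and contralateral hippocampus against contralateral cortex at 4 h. The groups, comparisons, tests, gene lists, the rule for named genes and the first set of alternatives were chosen before the data were examined.

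Gene lists, 26 in number, covered activity-regulated genes, stress responses, cytokines, cell type markers, receptors and channels, metabolism, cell cycle and region markers, and were tested with limma's camera (preset inter-gene correlation of 0.01, and an estimated correlation beside it) and with fry, adjusted over lists within a comparison. Fry asks whether a list's genes move on balance in one direction, or, in its mixed form, in either direction, without comparing the list with other genes. In list tests and counts each gene was represented by its probe set with the highest mean over all arrays, while a named gene is given by the highest-mean probe set among those past the threshold. Some genes belong to more than 1 list.

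Named genes were, for the 3 side comparisons, the 8 largest rises and the 8 largest falls among probe sets past the threshold that name 1 gene, and up to 3 members of each list past it with the largest change; for the other 5 comparisons these numbers were 5, 5 and 2. Where fewer passed, all were named; where none passed, the 5 with the smallest p were named as not past the threshold. List members that did not pass are named with their values only, and a probe set without a gene name in cortex at 24 h was named after its values were seen because only 8 had passed.

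Array quality was measured by the 3-prime to 5-prime ratios of the Gapdh and beta-actin controls, the 10th percentile of signal and the mean level of the bacterial spike-in controls, compared with exact two-sided permutation tests (24 tests, adjusted together; the smallest p that 7 arrays against 8 can give is 0.000155). Spread of list means was compared in the same way (78 tests). The procedure was tested on simulated data with the spread of these arrays, 200 changed among 7503 probe sets. For the side comparison in cortex at 4 h it recovered 59% of changes of 1.5-fold, 86.5% of 2-fold and 99% of 3-fold. In cortex at 24 h it recovered 63%, 89.5% and 99%, and in hippocampus 59.5%, 88.5% and 98.5%. The simulation drew errors independently for each probe set, with 1 SD per probe set over all groups, and did not apply the floor again. Variation that probe sets of an array share was left out, and falls of transcripts at the floor could count as recovered. The shares may therefore overstate what the real arrays can show. They are averages over simulated probe sets and do not hold for genes that vary widely between ipsilateral arrays. Ccl2, more than 3-fold higher in ipsilateral cortex at 4 h, varied in this way and did not pass. The absence of calls in that comparison therefore does not exclude changes of this size.

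Alternatives changed 1 choice at a time: quantile normalization, no filter on dim probe sets, a lower floor (53.1), an offset in place of the floor, the Gapdh ratio as a covariate, only the arrays of the groups compared, array weights, and leaving out each array. Chosen after seeing the data were the 10th percentile of signal as a covariate (for the hippocampal lists also with an estimated correlation), bright probe sets alone, and contralateral cortex at 24 h in place of 4 h for the region comparison. For each comparison, 100 splits of the same arrays, the real one included, were fitted. Raw image files were not analysed here.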

Results

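Gene expression was measured in rat brain after injury on 47 oligonucleotide arrays, each hybridised with total RNA from cortex or hippocampus of the side ipsilateral or contralateral to the injury. "HC" in the labels was read as hippocampus. Cortex was sampled at 4 h (7 ipsilateral and 8 contralateral arrays) and at 24 h (8 and 8), hippocampus at 4 h only (7 and 9). The labels do not separate sham-operated from injured animals, so the side comparisons are not comparisons of injured with uninjured tissue. Nothing in the labels says that the arrays are separate animals, so the p-values measure only the spread between these samples, which may be technical. The median signal per array ran from 615 to 879 and the 2%-trimmed mean from 2503 to 2504. The number of arrays limits the precision. Pearson's r across probe sets between arrays of a group lay between 0.944 and 0.985, and probe sets are not independent replicates. Of 7503 probe sets tested, the number past the threshold ranged from 0 to 2530 over 8 comparisons.

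**Figure D1:**
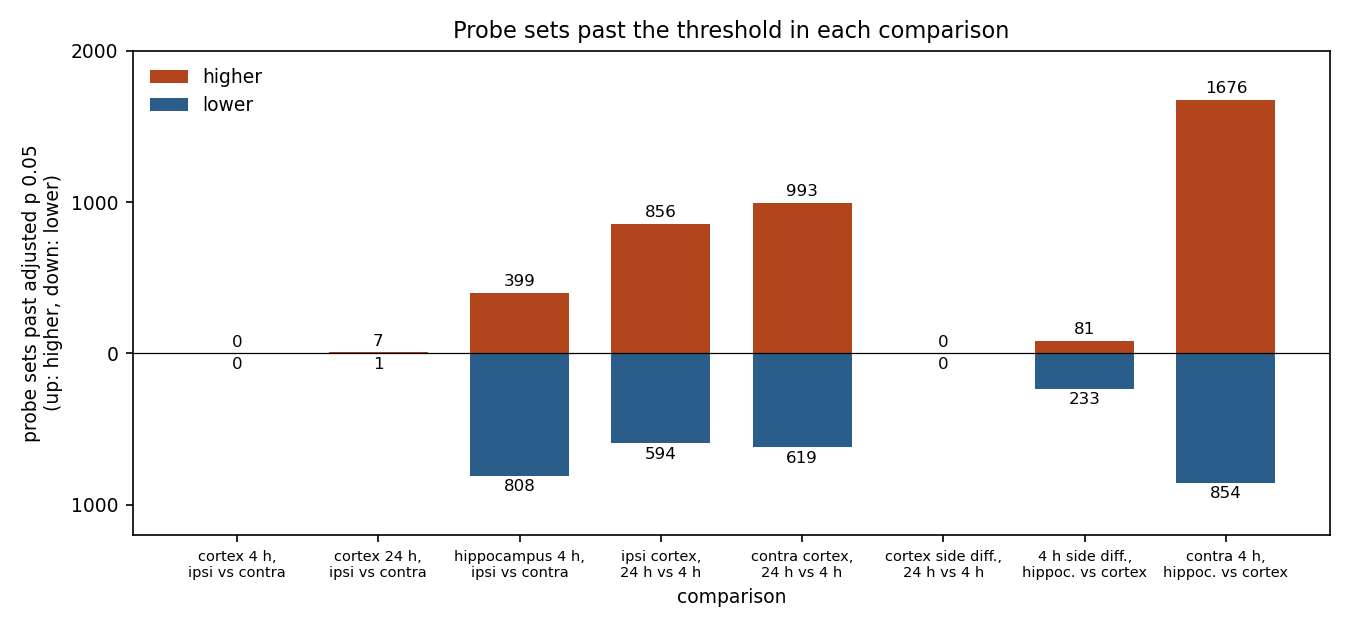
Number of probe sets past an adjusted p of 0.05 in each of the 8 comparisons, higher above the line and lower below it. Hippocampus against cortex on the contralateral side gave most (1676 higher, 854 lower), and the side comparison in cortex at 4 h gave 0.

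Cortex at 4 h was compared between sides to ask which transcripts the injured side carried at a higher or lower level early after injury. Ccl2, a chemokine that draws monocytes, averaged 10.35 ± 1.3 log2 signal (SD, n = 7) on the ipsilateral side and 8.58 ± 0.43 (n = 8) on the contralateral side, a difference of 1.76 (SE 0.56, 3.4-fold) that did not pass (limma adjusted p = 0.404). Cxcl10 was 1.54 (SE 0.43) and Ccl3 1.33 (SE 0.43) log2 units higher, also without passing. No probe set passed in limma (0 of 7503, smallest adjusted p 0.0599). At the unadjusted level 558 lay under an unadjusted p of 0.05 (288 higher, 270 lower) where 375 were expected by chance. Alternative settings of the same tool called between 0 and 5 probe sets. The genes with the smallest p were Chm (L13722_at, −0.97, SE 0.19, limma adjusted p = 0.0599), which takes part in Rab prenylation. Next were Myc (0.91, SE 0.21), Icam1 (1.22, SE 0.28), Itih4 (1.22, SE 0.28) and Junb (0.65, SE 0.16), each at a limma adjusted p of 0.134. Icam1, an adhesion molecule for leukocytes, and Itih4, an acute phase protein, were higher than the contralateral median on 7 of 7 ipsilateral arrays. Contralateral Myc and Itih4 were above the floor on only 1 of 8 arrays, so their differences are partly set by the floor.

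The cytokine list was higher as a set on the ipsilateral side of cortex at 4 h. Of its 31 measured genes 26 were higher, with a median difference of 0.34 (camera adjusted p = 1.55e-08, but adjusted p = 0.314 with an estimated correlation). Of its members, 0 passed over all probe sets and 4 rose when adjusted over the list alone, among them Icam1, Cxcl10, Ccl2 and Ccl3. Blood leukocyte markers were higher for 9 of 9 genes (median 0.07, camera adjusted p = 0.0425, adjusted p = 0.314 with an estimated correlation). Of these 0 passed over all and 2 adjusted over the list alone, the neutrophil calgranulins S100a8 (0.50, SE 0.15) and S100a9 (0.59, SE 0.21). Reactive astrocyte genes were higher for 15 of 19 (median 0.19, camera adjusted p = 0.019, adjusted p = 0.468 with an estimated correlation), with 0 past either way. Oligodendrocyte and myelin markers were lower for 13 of 13 genes, with a median of −0.20 (camera adjusted p = 0.00307, adjusted p = 0.468 with an estimated correlation) and 0 past either way. Among them Mobp (−0.24, SE 0.12), Mog (−0.24, SE 0.15), Cnp (−0.21, SE 0.12) and Mag (−0.21, SE 0.14) encode myelin proteins. Adjusted over the list alone, 2 erythroid and plasma protein genes were higher. The haemoglobin gene Hbb differed by 0.43 (SE 0.15, limma adjusted p = 0.429 over all probe sets).

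**Figure D2:**
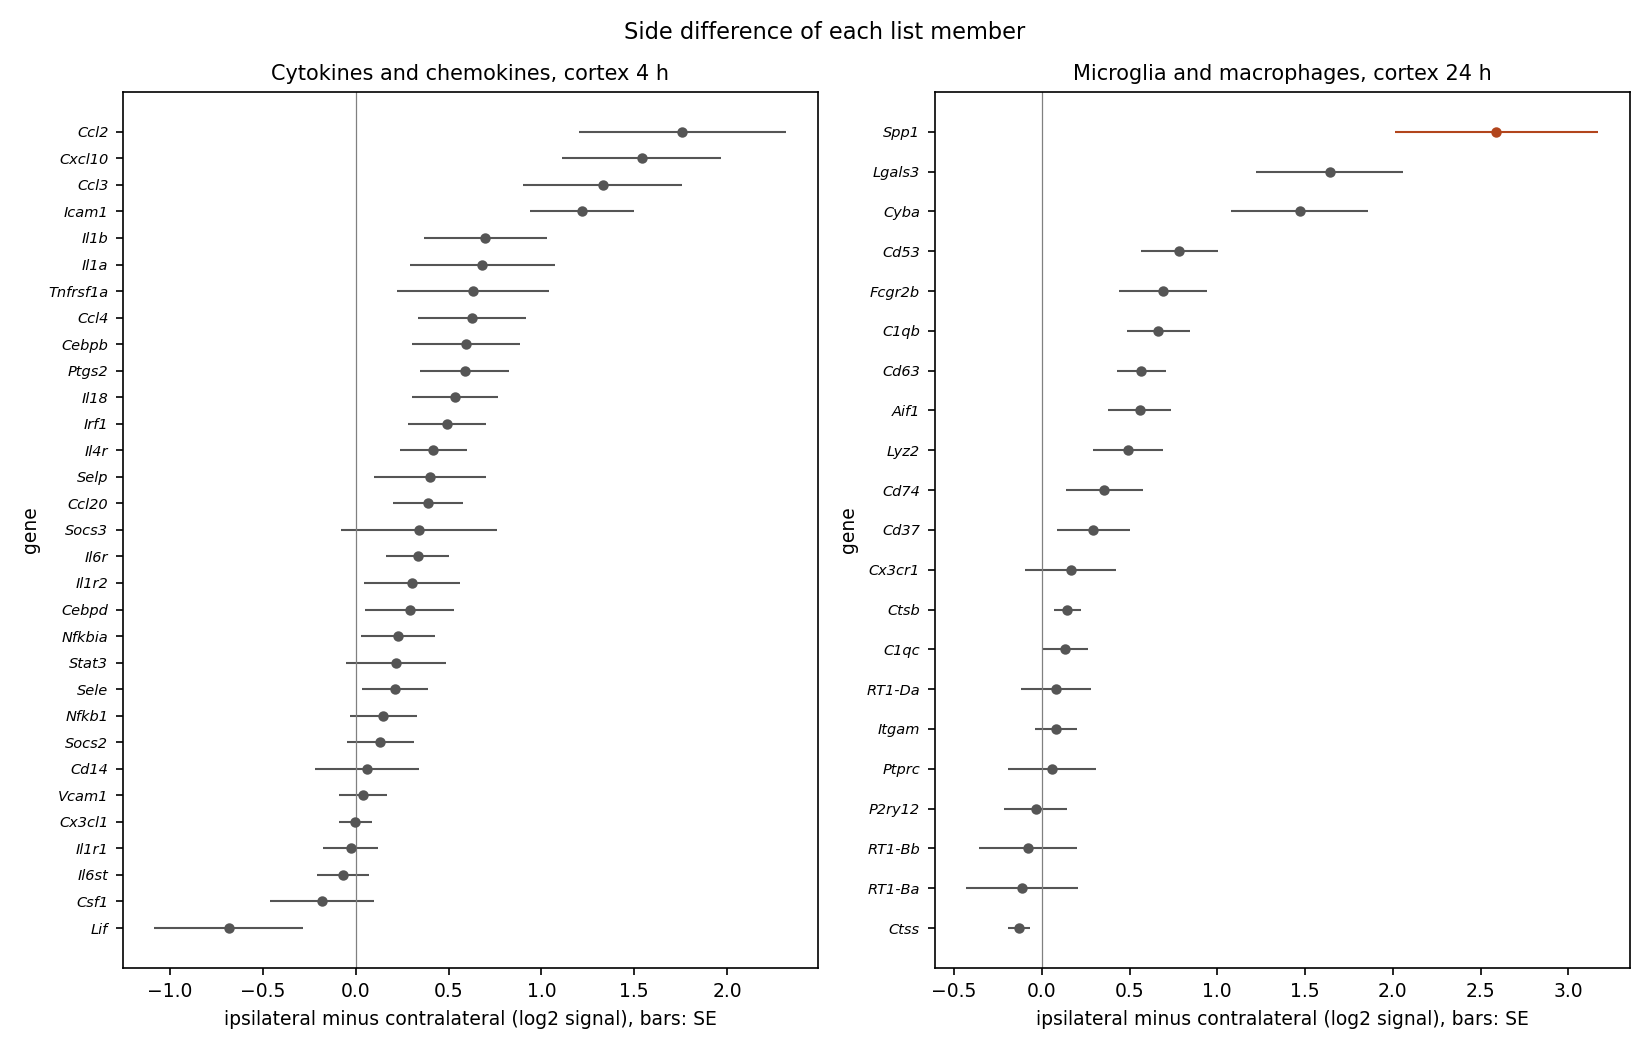
Ipsilateral minus contralateral log2 signal of each measured member of the cytokine list in cortex at 4 h (31 genes) and of the microglia list in cortex at 24 h (21 genes), with SE as bars; red marks a gene past an adjusted p of 0.05 over all probe sets. Cytokine members run up to 1.76 (Ccl2) and microglia members up to 2.59 (Spp1).

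The same side comparison at 24 h asked which changes were present a day after injury. Spp1 (osteopontin, M14656_at), a matrix protein made by activated microglia and macrophages, rose by 2.59 log2 units (SE 0.58, 6.02-fold, limma adjusted p = 0.0498), from 7.85 ± 0.41 to 10.44 ± 2.5 (SD, n = 8 and 8). The SE and p rest on a spread pooled over all 6 groups, which is smaller than that of these ipsilateral arrays. Spp1 was higher than the contralateral median on 6 of 8 ipsilateral arrays. The small heat shock protein gene Hspb1 (rc_AA998683_g_at) rose by 1.98 (SE 0.43, 3.96-fold) and was higher on 8 of 8 arrays, but 1 of its 4 probe sets passed. Top2a, a DNA topoisomerase of dividing cells, rose by 0.84 (SE 0.19, 1.8-fold), and the ribosomal protein gene Rpl21 by 0.40 (SE 0.088, 1.32-fold). The Rpl21 probe set with the highest mean over all arrays did not pass. The kinase gene Matk fell by 0.38 (SE 0.081, 1.3-fold). These 5 genes and 3 probe sets without a single gene name made up the 8 calls (7 higher, 1 lower), all at a limma adjusted p of 0.0498. The count was 0 without the filter on dim probe sets or with the arrays of the compared groups alone, 38 with array weights, and 0 on leaving out any of 10 of the 16 arrays (37, 38, 39, 40, 42, 43, 44, 45, 46 or 48). In all 575 probe sets lay under an unadjusted p of 0.05 (375 expected). The probe sets without a gene name all rose, AF028784cds#1_s_at by 1.37 (SE 0.29).

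Microglia and macrophage markers were higher as a set in ipsilateral cortex at 24 h (17 of 21 genes, median 0.29, camera adjusted p = 7.27e-10, and adjusted p = 0.0137 with an estimated correlation). The rise lay in some of the arrays: 4 of 8 ipsilateral arrays (37, 38, 39 and 40) had a mean of the microglia and macrophage markers above the highest contralateral one of 0.0933, from 0.697 to 1.03, and the others lay between −0.0823 and 0.0559. Of the 21 genes, 1 rose over all probe sets (Spp1), 20 did not pass, and 9 rose when adjusted over the list alone. Lgals3, a lectin of phagocytes, was 1.64 (SE 0.42) higher, the NADPH oxidase subunit Cyba 1.47 (SE 0.39) and the complement gene C1qb 0.67 (SE 0.18), with limma adjusted p of 0.111, 0.122 and 0.122 over all probe sets. Reactive astrocyte genes were higher for 13 of 19 (median 0.39, camera adjusted p = 2.43e-05, adjusted p = 0.123 with an estimated correlation), with 0 past over all and 7 adjusted over the list alone. The intermediate filament Vim was 0.74 (SE 0.20) and the protease inhibitor Serpina3n 1.02 (SE 0.28) higher. Cell cycle genes were higher for 13 of 18 (median 0.11, camera adjusted p = 0.000259, adjusted p = 0.123 with an estimated correlation). Of these 1 rose over all (Top2a) and 4 rose adjusted over the list alone. The kinase Cdk1 was 0.82 (SE 0.23) and the replication factor Mcm6 0.55 (SE 0.16) higher. Extracellular matrix genes (15 of 26 higher, median 0.04, camera adjusted p = 0.0239, adjusted p = 0.264 with an estimated correlation) and interferon response genes (12 of 14 higher, median 0.06, adjusted p = 0.0423, adjusted p = 0.262 with an estimated correlation) were higher by small amounts. Cholesterol synthesis genes were lower (1 of 14 higher, median −0.11, adjusted p = 0.0465, adjusted p = 0.754 with an estimated correlation). None of these 3 lists had a member past either way. As for microglia, 4 of 8 ipsilateral arrays lay above the highest contralateral array in the list mean of reactive astrocyte genes, of cell cycle genes and of matrix genes, and 5 of 8 in that of interferon response genes. The cytokine list, higher at 4 h, was not called at 24 h (18 of 31 higher, camera adjusted p = 0.716).

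**Figure D3:**
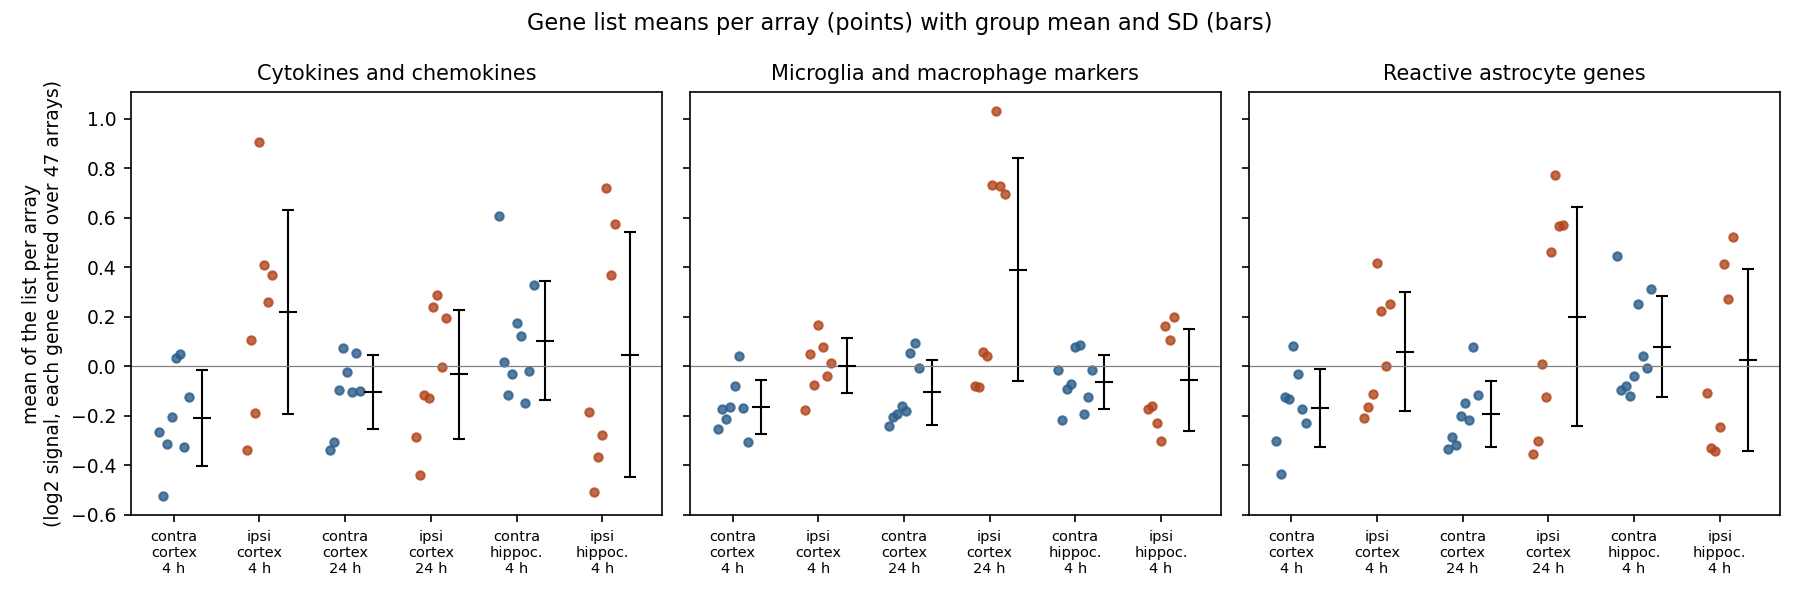
Mean of each array over 3 gene lists (log2 signal, each gene centred over the 47 arrays), with points for arrays and bars for the group mean and SD. In cortex at 24 h the microglia means ran from −0.0823 to 1.03 on the ipsilateral side and from −0.242 to 0.0933 on the contralateral side.

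The spread of the list means between arrays was compared as well, with an exact permutation test of absolute deviations from the group median in 78 combinations of list and side comparison. Only 2 passed after adjustment, both in cortex at 24 h and both wider on the ipsilateral side. Microglia and macrophage markers had an SD of 0.45 against 0.13 (n = 8 and 8, exact p = 0.000155, adjusted 0.0121), and reactive astrocyte genes 0.44 against 0.13 (exact p = 0.000466, adjusted 0.0182). The cytokine list had an SD of 0.41 against 0.19 in cortex at 4 h, which did not pass (adjusted 0.68). Its arrays ran from −0.337 to 0.904 on the ipsilateral side and from −0.525 to 0.0488 on the contralateral side. In hippocampus it had an SD of 0.49 against 0.24, which did not pass (adjusted 0.648), with arrays from −0.509 to 0.719 on the ipsilateral side and from −0.149 to 0.605 on the contralateral side.

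Hippocampus at 4 h was compared between sides to ask which transcripts differed in a region beneath the cortex. The transcriptional co-regulator Cited2 (rc_AA900476_at) rose by 1.60 log2 units (SE 0.35, 3.04-fold, limma adjusted p = 0.00199) from 8.92 ± 0.87 (SD, n = 9) to 10.52 ± 0.15 (n = 7). The forkhead factor gene Foxe3 (L13207_at) fell by 1.86 (SE 0.31, 3.62-fold, adjusted p = 0.000252) from 10.13 ± 0.32 to 8.27 ± 0.6. Both differences held on 7 of 7 ipsilateral arrays. In all, 1207 probe sets passed, 399 higher and 808 lower (33.1% higher, 883 genes). The excess of falls lay mostly in dim probe sets. Among probe sets with a mean up to the median of those tested 106 were higher and 444 lower, among the brighter ones 293 and 364. With quantile normalization the share higher was 46.2% of 1083. The 10th percentile of signal was lower on the ipsilateral arrays (44 ± 6.9 against 64.8 ± 16, log2 difference −0.54, exact p = 0.00253, adjusted 0.00867 over 24 tests). With it as a covariate only 5 probe sets passed, so the differences in this comparison cannot be separated from that intensity difference. Further rises of the largest size were Zbtb24 (1.41, 2.66-fold), Arl2 (1.32, 2.5-fold), Flnc (1.25), Lamp1 (1.20), the calcium channel Itpr1 (1.18), Igf2r (1.09) and Crispld2 (1.04). Further falls were the olfactory receptor Or8g20b (−1.70, 3.25-fold), the translation repressor Eif4ebp1 (−1.46, 2.76-fold), P2ry4 (−1.42), Gtf2ird1 (−1.42), Afm (−1.40), Grk4 (−1.40) and Pax4 (−1.37).

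Among the hippocampal gene lists, 0 of 26 were called by camera in this comparison (0 with an estimated correlation as well), while single members passed in both directions. Counts of list members in hippocampus are to be read against the 1207 of all 7503 probe sets that passed. Of 25 immediate early and activity-regulated genes, 4 rose and 2 fell over all probe sets (4 and 2 adjusted over the list alone, camera adjusted p = 0.254), with Egr1 at 0.56 (SE 0.15) and Egr4 at −0.79 (SE 0.19). Probe sets other than those counted rose for Fos (0.74, SE 0.25, limma adjusted p = 0.0376) and Crem (0.85, SE 0.21), which neuronal activity induces. With the 10th percentile of signal as a covariate this list (camera adjusted p = 0.00238) and the cytokine list (0.00264) were called as higher, but both calls were lost (adjusted p = 0.518 with an estimated correlation for each). Of 31 cytokine and signalling genes 3 fell (2 adjusted over the list alone), the transcription factor Cebpd among them (−1.14, SE 0.23, limma adjusted p = 0.00123) and the decoy receptor Il1r2 (−0.71, SE 0.25). A probe set of Cebpb other than the one counted rose by 0.96. Voltage-gated ion channels divided, with 3 of 35 higher and 3 lower (the same numbers adjusted over the list alone, camera adjusted p = 0.72, fry mixed adjusted p = 8.82e-07). The mixed test does not compare the list with other genes, many of which also differed, so it does not single out channels. The potassium channel Kcnd3 rose by 1.01 (SE 0.17, adjusted p = 0.000341), and the calcium channel subunits Cacna1e (−0.88, SE 0.20) and Cacnb1 (−0.77, SE 0.16) fell. In the GABA system 3 of 24 rose and 2 fell (3 and 2 adjusted over the list alone), with the receptor subunits Gabra4 at 0.49 (SE 0.17) and Gabra6 at −0.75 (SE 0.22). Another probe set of Gabbr1 rose by 1.02 (SE 0.25). Of 23 glutamate receptor and transporter genes 1 fell (0 adjusted over the list alone), while other probe sets of the receptors Grin2c (0.43) and Grin1 (0.40) rose and another of the transporter Slc1a2 (−0.53) fell.

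Among glial and blood markers in hippocampus, 1 of 21 microglia genes (1 adjusted over the list alone), 2 of 19 reactive astrocyte genes (2), 1 of 11 astrocyte homeostatic genes (0), 1 of 9 leukocyte genes (1) and 1 of 9 erythroid and plasma protein genes (2) fell over all probe sets. Examples were the complement gene C1qc (−0.43, SE 0.13), the filament Nes (−0.60, SE 0.14), the T cell kinase Lck (−0.98, SE 0.19) and the anion exchanger Slc4a1 (−0.67, SE 0.16). Of 13 endothelial and of 15 choroid plexus markers 2 each fell (2 and 2 adjusted over the list alone), including Flt1 (−0.76) and Prlr (−1.13). Of 13 oligodendrocyte markers 0 passed either way. Of 26 matrix genes 1 rose and 2 fell (0 and 2 adjusted over the list alone). Tnc, a matrix glycoprotein, fell by 1.34 (SE 0.41), and Mmp2 fell by 1.09 (SE 0.30). Of 18 cell cycle genes 1 rose and 2 fell (the same adjusted over the list alone), with the replication factor Mcm7 at −0.57 (SE 0.14). Another probe set of the cyclin Ccnd1 fell by 1.09 (SE 0.21, limma adjusted p = 0.000642). Of 15 apoptosis genes 3 fell (3, and 2 rises, adjusted over the list alone), with the survival gene Bcl2 at −0.83 (SE 0.18). Heat shock genes had 1 of 16 lower (1 adjusted over the list alone), Hspb1 by −0.95 (SE 0.22) in 1 of its 4 probe sets. Other probe sets of Hsph1 (0.68) and Hspa4 (0.57) rose.

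The remaining hippocampal lists had few members past the threshold. Of 14 cholesterol genes 2 rose and 1 fell (3 and 1 adjusted over the list alone; Idi1 0.60, Mvk −0.33), and of 17 glycolysis genes 2 fell (1; Hk2 −0.69). Of 18 oxidative phosphorylation genes 1 rose (1; Ndufa5 0.35), and of 14 interferon genes 2 fell (2; Oas1a −0.61). Of 30 growth factor genes 1 rose and 1 fell (1 rise adjusted over the list alone), while other probe sets of Pdgfb (0.93) rose and of Igf1r (−0.64) fell. Of 28 neuronal and synaptic genes 2 rose (1; another probe set of the neurofilament Nefh by 0.50). Of 20 metallothionein and oxidative stress genes 0 passed either way, although other probe sets of Sod1 (−0.65) and Gsr (0.89) did. Of 9 hippocampus-enriched markers 2 rose and 1 fell (the same adjusted over the list alone). The synaptic pentraxin Nptx1 rose by 0.64 (SE 0.13) in 1 probe set and passed the other way in another. Of 7 cortex-enriched markers 2 rose (2), including the interneuron calcium buffer Pvalb (0.43, SE 0.11).

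**Figure D4:**
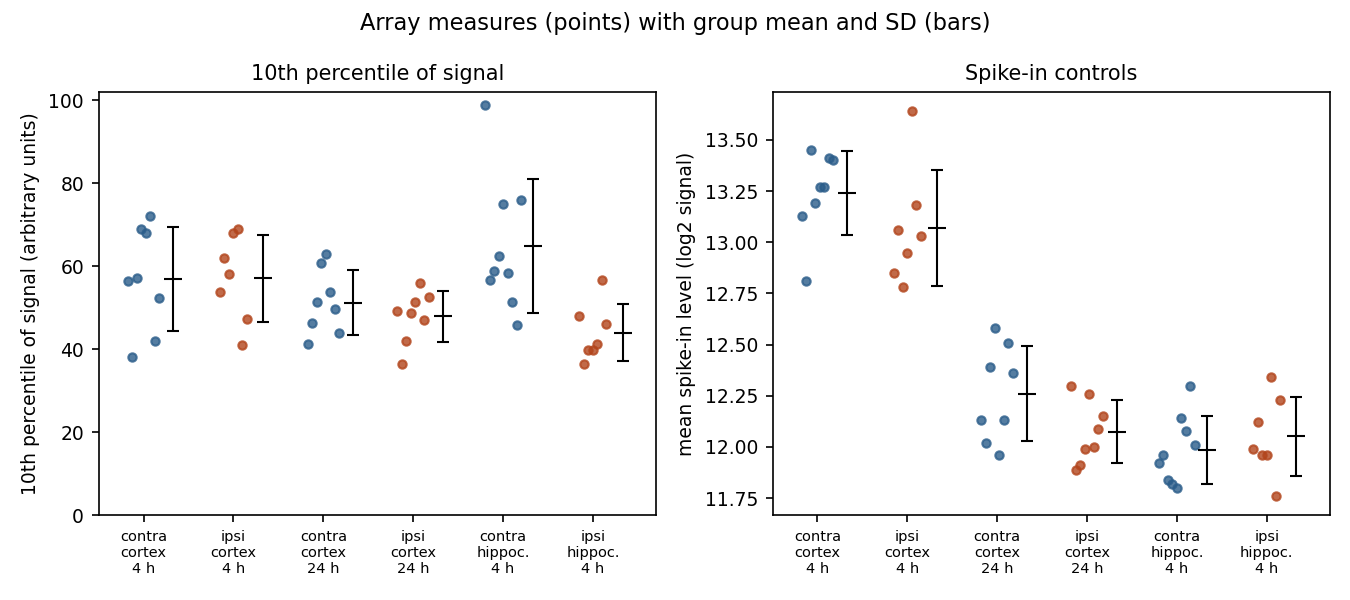
The 10th percentile of signal and the mean log2 signal of the bacterial spike-in controls on each array (points), with group mean and SD (bars). In hippocampus the ipsilateral arrays lay between 36.4 and 56.7 and the contralateral arrays between 45.8 and 98.9 on the first measure; the 4 h cortex groups had the highest spike-in means (13.07 and 13.24).

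Ipsilateral cortex at 24 h was compared with ipsilateral cortex at 4 h to follow the response over time. The astrocyte water channel Aqp4 (U14007_at) rose 2.82-fold (SE 0.19 log2 units, limma adjusted p = 3.24e-07), from 10.67 ± 0.35 log2 signal (SD, n = 7) to 12.16 ± 0.49 (n = 8). It was higher on 8 of 8 arrays. The early chemokines fell: Cxcl10 by 1.40 (SE 0.43, 2.64-fold, adjusted p = 0.0159) and Ccl3 by 1.25 (SE 0.43, 2.38-fold, adjusted p = 0.0344). So did Cebpd (−1.45) and the lipid enzymes Ephx2 (−1.39) and Pla1a (−1.17). Other large rises were H19 (1.48), the signalling inhibitor Smad7 (1.46), Prpsap1 (1.42) and the receptor Fgfr2 (1.41). In all 1450 probe sets passed, 856 higher and 594 lower (59% higher, 50.3% of 1292 with quantile normalization), and 737 with the Gapdh 3-prime to 5-prime ratio as a covariate. The arrays also differed technically. Spike-in controls differed by −0.999 log2 units, 24 h minus 4 h (exact p = 0.000155, adjusted 0.00119). The Gapdh 3-prime to 5-prime ratio differed by −0.133 (exact p = 0.00668, adjusted 0.0178) and that of beta-actin by −0.183 (exact p = 0.00653, adjusted 0.0178). Time and such technical differences, a possible array batch included, therefore cannot be told apart here. The labels give no batch.

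Oxidative phosphorylation genes were lower at 24 h on the ipsilateral side (14 of 18, median −0.22, camera adjusted p = 5.99e-05, adjusted p = 0.00289 with an estimated correlation, 0.0915 with quantile normalization). Over all probe sets 9 fell, 1 rose and 8 did not pass (9 and 1 adjusted over the list alone), with the complex I subunits Ndufv2 at −0.65 (SE 0.12) and Ndufs1 at 0.66 (SE 0.15). Cholesterol synthesis genes were lower as well (11 of 14, median −0.30, camera adjusted p = 0.00731, adjusted p = 0.592 with an estimated correlation). Of these 6 fell, 0 rose and 8 did not pass, and 7 fell adjusted over the list alone. Mvd (−0.60, SE 0.15) and Insig1 (−0.49, SE 0.14) were among them. Of 31 cytokine genes 5 fell, Cxcl10 and Ccl3 among them, and 1 rose (the same adjusted over the list alone, camera adjusted p = 0.13). Of 21 microglia genes 5 rose and 0 fell (7 adjusted over the list alone, camera adjusted p = 0.0747), with the leukocyte phosphatase Ptprc at 0.92 (SE 0.26). Another probe set of the MHC class II gene RT1-Ba rose by 1.23 (SE 0.34). The growth factor Bdnf rose by 1.13 (SE 0.19, limma adjusted p = 3.32e-05) in 1 of its 7 probe sets. Rises were also measured for the AMPA receptor genes Gria4 by 1.27 (SE 0.22) and Gria2 by 0.89 (SE 0.12), the collagen Col1a1 by 1.07 (SE 0.14), the chaperone Hspa5 by 1.18 (SE 0.21) and Top2a by 0.98 (SE 0.19). The neutrophil marker S100a8 fell by 0.57 (SE 0.15), and Myc fell by 0.80 (SE 0.21).

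The contralateral cortex was compared between the same times to see which changes occurred on both sides. The lipid enzyme Gpam (U36773_at) rose by 2.20 (SE 0.32, 4.61-fold, limma adjusted p = 1.69e-06, n = 8 and 8), the glial potassium channel Kcnj10 by 1.58 (SE 0.27, 3-fold), Eif4ebp1 by 1.69, Grk4 by 1.37 and Pomc by 1.36. Gsr, glutathione reductase, fell by 1.49 (SE 0.28, 2.8-fold, adjusted p = 9.94e-05), followed by Ephx2 (−1.33), Arl2 (−1.20), Eef2k (−1.18) and Sema6b (−1.17). In all 1612 probe sets passed, 993 higher and 619 lower (61.6% higher, 51.1% with quantile normalization). With the Gapdh ratio as a covariate 601 passed, 555 of them shared. Aqp4 (1.20), Gria2 (0.92) and Col1a1 (1.05) rose here too. Across the 7503 probe sets the time differences of both sides correlated with Pearson's r of 0.666 (probe sets are not independent). On both sides 561 rose and 372 fell, where 113 and 49 were expected by chance. In opposite directions 0 passed in limma, although the test of the difference itself had 421 at an unadjusted p under 0.05. Spike-in controls differed by −0.978, 24 h minus 4 h (exact p = 0.000155, adjusted 0.00119), and the Gapdh ratio by −0.168 (exact p = 0.000466, adjusted 0.00186), so this comparison is confounded with a possible array batch in the same way.

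Oxidative phosphorylation genes were also lower at 24 h on the contralateral side (14 of 18, median −0.17, camera adjusted p = 0.00019, adjusted p = 0.00565 with an estimated correlation, 0.339 with quantile normalization). Of these 9 fell, 2 rose and 7 did not pass, with the same numbers adjusted over the list alone. Ndufv2 fell by 0.57 (SE 0.11). In the GABA system 11 of 24 rose, 3 fell and 10 did not pass (11 and 3 adjusted over the list alone, camera adjusted p = 0.444). The rises included the GABA-synthesising enzyme Gad2 (0.78, SE 0.15) and the GABA transaminase Abat (0.80, SE 0.16). Of 35 ion channel genes 7 rose and 3 fell (9 and 3 adjusted over the list alone, camera adjusted p = 0.593), with Kcnc2 at 0.94 (SE 0.16) and Scn1a at 0.92 (SE 0.21). Myelin basic protein, Mbp, fell by 0.41 (SE 0.078), Apoe fell by 0.31 (SE 0.059) and C1qb fell by 0.54 (SE 0.18).

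Whether the side difference in cortex changed between 4 h and 24 h was tested as an interaction. No single gene passed in limma (0 of 7503, smallest adjusted p 0.279), with 421 at an unadjusted p under 0.05 (375 expected) and 0 or 1 under the alternative settings. The genes with the smallest p were Akt1 (0.53, SE 0.12), Gyg1 (0.66, SE 0.16), Sv2a (0.54, SE 0.13), Cngb1 (−1.45, SE 0.35) and Top2a (1.08, SE 0.27), each at a limma adjusted p of 0.279. Among the lists, the cytokine difference was smaller at 24 h than at 4 h (26 of 31 genes, median −0.29, camera adjusted p = 0.00134) and the microglia difference larger (16 of 21, median 0.26, 0.00519). The oligodendrocyte difference was less negative (12 of 13, median 0.17, 0.00519) and the cholesterol difference lower (12 of 14, median −0.19, 0.0082). Each of these 4 calls was lost with an estimated correlation (adjusted p = 0.465 with an estimated correlation in all 4). Of their members 0 passed either over all or adjusted over the list alone.

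The side difference at 4 h was compared between hippocampus and cortex in the same way, and 314 probe sets passed (81 higher, 233 lower, 25.8% higher, 36.7% of 297 with quantile normalization). The count was 64 with the arrays of the compared groups alone and ran from 135 to 508 on leaving out single arrays (5 and 14). Foxe3 differed by −2.32 (SE 0.45, limma adjusted p = 0.00438), with a side difference of −1.86 in hippocampus and 0.46 in cortex. Cited2 differed by 2.16 (SE 0.50, adjusted p = 0.012), with 1.60 in hippocampus and −0.56 in cortex. The activity-regulated genes Crem (1.49, SE 0.30) and Homer1 (1.09, SE 0.20), a synaptic scaffold, had the larger side difference in hippocampus, and Icam1 (−1.36, SE 0.39) the larger in cortex. The values of Crem and Homer1 come from probe sets other than that with the highest mean, which did not pass. Contralateral hippocampal Crem lay near the floor of 7.54 (7.54 to 7.88 apart from array 28). The cytokine list differed (27 of 31 lower, median −0.43, camera adjusted p = 0.0367, adjusted p = 0.613 with an estimated correlation). It had 2 members lower, 0 higher and 29 not past (2 adjusted over the list alone), Cebpd (−1.43) and Icam1. Neuronal and synaptic genes (20 of 28 higher, median 0.12, 0.038, adjusted p = 0.577 with an estimated correlation) and oligodendrocyte genes (10 of 13 higher, median 0.31, 0.029, adjusted p = 0.599 with an estimated correlation) had 0 members past either way by the probe set counted. The intensity difference of the hippocampal arrays enters here as well: with the 10th percentile of signal as a covariate, 1 probe set passed.

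Contralateral hippocampus was compared with contralateral cortex at 4 h as a test of the region labels. The mineralocorticoid receptor Nr3c2 (1.88, SE 0.14, 3.67-fold, limma adjusted p = 4.67e-15, n = 9 and 8) and the granule cell factor Neurod1 (1.66, SE 0.13, 3.15-fold), both enriched in hippocampus, were higher there. Pvalb (−1.38, SE 0.10, 2.6-fold) and Egr1 (−1.51, SE 0.15, 2.86-fold) were lower than in cortex. The largest differences were Gpr161 (2.80, SE 0.13, 6.98-fold), Gpam (2.33), Sncg (2.28), Doc2b (2.17) and the serotonin receptor Htr2c (2.10) on the higher side, and the potassium channel Kcns1 (−2.93, SE 0.13, 7.63-fold), Olr59 (−2.38), Medag (−2.17), the kinase inhibitor Camk2n1 (−2.07) and Tnnc2 (−2.06) on the lower side. In all 2530 probe sets passed, 1676 higher and 854 lower (66.2% higher). With quantile normalization 2041 passed with 49.3% higher, and the median difference of all probe sets was 0.0102 in place of 0.112 (median of the single shifts −0.143). Against contralateral cortex at 24 h in place of 4 h, 1483 passed (768 higher, 715 lower), with 33.4% of the 2530 called in the same direction. Spike-in controls differed by −1.26 log2 units, hippocampus minus cortex (exact p = 4.11e-05, adjusted 0.000986). The Gapdh ratio differed by −0.156 (exact p = 0.000247, adjusted 0.00119) and the beta-actin ratio by −0.293 (exact p = 0.000206, adjusted 0.00119). Region and such technical differences, a possible array batch included, therefore cannot be told apart for single genes or gene lists within 4 h. Mean spike-in level was 11.99 in contralateral hippocampus, 12.26 in contralateral cortex at 24 h and 13.24 in that at 4 h. The 24 h cortex is thus closer in this measure but differs in time. Gpam rose between the times in contralateral cortex by nearly as much as it differed here. Its difference therefore lay mostly between the 4 h cortex arrays and both other groups.

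Of 9 hippocampus-enriched markers 4 were higher, 1 lower and 4 did not pass (5 and 1 adjusted over the list alone; median 0.55, camera adjusted p = 0.0472, adjusted p = 0.0631 with an estimated correlation). Of 7 cortex-enriched markers 4 were lower, 2 higher and 1 did not pass (the same adjusted over the list alone; median −0.71, adjusted p = 0.00553, adjusted p = 0.0223 with an estimated correlation). Oxidative phosphorylation genes were lower in hippocampus (12 lower, 0 higher, 6 not past; 14 lower adjusted over the list alone; median −0.32, camera adjusted p = 1.21e-08, adjusted p = 3.62e-05 with an estimated correlation). Atp5po was among them (−0.61, SE 0.082). The mean of this list ran from 0.0959 to 0.193 on contralateral cortex arrays at 4 h and from −0.0543 to 0.0269 at 24 h. In contralateral hippocampus it ran from −0.22 to −0.06. The hippocampal arrays thus lay below both cortex groups, but part of the difference lay between the 4 h cortex arrays and both other groups. Neuronal and synaptic genes were lower (10 lower, 4 higher, 14 not past, the same adjusted over the list alone; median −0.17, camera adjusted p = 0.000397, adjusted p = 0.0461 with an estimated correlation, 0.463 with quantile normalization). Examples were the vesicle fusion gene Stx1a (−1.14, SE 0.068) and the kinase Camk2g (−1.04, SE 0.089). Immediate early genes were lower (10 lower, 3 higher, 12 not past, the same adjusted over the list alone; median −0.25, camera adjusted p = 0.002, adjusted p = 0.214 with an estimated correlation), with Egr2 at −1.71 (SE 0.28) and the phosphatase Dusp1 at −1.56 (SE 0.18). The AMPA receptor gene Gria1 (1.65, SE 0.09), the GABA receptor gene Gabra5 (1.57, SE 0.14), the neurotrophin Ntf3 (1.82, SE 0.21) and the receptor Fgfr1 (1.30, SE 0.11) were higher in hippocampus, while the GABA receptor gene Gabrd was lower (−1.52, SE 0.12).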

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

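Of the tests in this part, those of array batch by the spike-in controls and of the label of array 23 were chosen after their results had been seen, and the 10th percentile of signal as a covariate is an alternative added after seeing the data.

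The side difference in hippocampus at 4 h (1207 probe sets, led by Cited2 and Foxe3) came with a lower 10th percentile of signal on the ipsilateral arrays. Whether array 23 carries a wrong label stays open, since 0.919 of the count was left without it (1109, against 870 to 1427 without each other contralateral array) and its other measures divide. Its first principal component (25.4, other contralateral 15.3 to 33.9, ipsilateral at most 14.1) and second (−4.01, ipsilateral 8.15 to 26.6) run with its label. Its 10th percentile (98.9, other contralateral 45.8 to 75.9, ipsilateral at most 56.7) and beta-actin ratio (0.0857, 0.174 to 0.441, ipsilateral at least 0.212) lie outside its group, away from the ipsilateral arrays. Also outside its group lie its Gapdh ratio (0.222, other contralateral 0.0297 to 0.158, ipsilateral up to 0.252) and its mean of the cytokines, chemokines and their immediate signalling (0.605, other contralateral at most 0.328). So do the third component (17.1, other contralateral −0.147 to 6.45, ipsilateral up to 15.9) and the fourth (−11.9, other contralateral −0.44 to 10.1, ipsilateral arrays 21, 22 and 24 −14.1 to −7.81, arrays 17 to 20 2.31 to 8.19). An intensity difference between the arrays stays open: with the 10th percentile as a covariate the slope of the adjusted on the unadjusted differences was 0.546 (95% interval 0.531 to 0.561), where a slope over 0.75 was set to count against it. The interval is too narrow, since the probe sets share the same arrays and were picked by their unadjusted differences. The median size of the called differences went from 0.588 (median SE 0.169) to 0.274 (0.172), so the calls ended because the differences shrank, although 1198 of the 1207 (99.3%) kept their direction. Quantile normalization, which gives every array the same distribution of signal, left 1083 calls in place of 5, of which 925 were among the 1207. Only 3 of 7 ipsilateral and 3 of 9 contralateral arrays lay in the shared range of 45.8 to 56.7, which keeps the intensity difference and the side, the biological explanation, from being told apart.

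The differences between 24 h and 4 h in cortex (1450 ipsilateral and 1612 contralateral probe sets, Aqp4 and Gria2 among both) may reflect an array batch as well as time. The spike-in controls, added during processing and not made by the tissue, differed by −0.994 log2 units over 16 and 15 arrays (SD within groups 0.22, permutation p = 1e-05, the smallest that 100000 resamples can give). The highest 24 h array (12.58) lay under the lowest 4 h array (12.78), so spike-in level is fully confounded with time in cortex. No time difference at a shared spike-in level can be had. The labels give no batch, so a batch is inferred from this level alone. The hippocampal arrays at 4 h had group means of 12.05 and 11.99, near the 24 h cortex arrays, so the level did not follow time over both regions. Nothing tested argues against either explanation. The time after injury stays open as the biological explanation.

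The pooled variance of the cytokine list mean was 3.91 times as large within ipsilateral as within contralateral groups (Ccl3 6.2, Ccl2 4.34, Cxcl10 2.97), although none of the 3 single comparisons passed (adjusted exact p 0.68, 0.645 and 0.648). A spread of all genes alike is argued against, since random lists matched on mean expression had a median of 0.996 and a 95th percentile of 1.94 (0 of 1000 as high as 3.91). Genes of random lists need not vary together as those of a fixed list may, so this cannot exclude a spread shared by many lists. Other lists were wide too, among them microglia markers (6.84), ion channels (3.3), glutamate receptors (3.22) and neuronal genes (3.05). RNA quality is argued against as well, since the ratio was 6.42 with both 3-prime to 5-prime ratios as covariates. Blood in the tissue could contribute and stays open, with a ratio of 2.21 for 4 erythroid genes (Hbb 2.93, Hbb-b1 2.16, Alas2 1.19, Slc4a1 0.885). The whole erythroid and plasma protein list had 0.7. That list includes Ttr, a product of the choroid plexus that varied widely within every group, so its ratio cannot decide about blood. The labels name no treatment within a group, so no biological explanation was tested; animals that differ in injury, sham operation included, are a possible explanation that stays open.

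Other splits of the same arrays into groups of the same sizes were fitted for each comparison, 100 each with the real one included. A share of splits under 0.05 was taken to argue against chance, without adjustment over the 8 comparisons, and 100 splits cannot exclude it. For the side comparison in cortex at 24 h 1 of 100 gave as many calls as the real 8, the real one itself (highest other 7), which argues weakly against chance. The real count exceeded the highest other by 1 call, and it was 0 with the arrays of the compared groups alone and without array 37, 38, 39, 40, 42, 43, 44, 45, 46 or 48. For hippocampus 2 of 100 gave as many calls as the real split (real 1207, highest other 1271), which argues against chance. The other split with more calls than the real one had 6 of the 7 ipsilateral arrays in its first group, and its groups differed in the 10th percentile by −0.572 log2 units. Chance is also argued against for the time comparison on the ipsilateral side (1 of 100, real 1450, highest other 1093) and on the contralateral side (1 of 100, real 1612, highest other 676). The same holds for the difference between regions in the side difference (1 of 100, real 314, highest other 10) and for the region comparison (1 of 100, real 2530, highest other 1331). For the side comparison in cortex at 4 h and the change of the cortical side difference with time the real count was 0, so 100 of 100 splits gave as many by construction and nothing about chance was tested. The highest other split in the first of these called 629 and 9 splits called over 100, which points to a structure of the samples other than side. The groups of that split differed in the 10th percentile by −0.376 log2 units, where the real sides differed by 0.0149. For the change of the side difference with time the highest other split called 22.

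Single arrays far from the rest of their group were found in 24 of 360 groups of values, where chance gives about 1 in 20, or 18, for normally distributed values. Among list means there were 5 of 156 (7.8 by chance), all of them lowest in their group. Array 23 of contralateral hippocampus had −0.216 for heat shock genes (others −0.0659 to 0.0837). Array 34 of ipsilateral cortex at 24 h had −0.486 for astrocyte homeostatic markers (others 0.00943 to 0.258) and −0.257 for glutamate receptors and transporters. Array 7 of ipsilateral cortex at 4 h had −0.469 for the glutamate list, and array 11 of contralateral cortex at 4 h had −0.255 for the GABA list.

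Among named genes 19 of 180 groups had such an array, against 9 by chance. Several of these groups had arrays at the floor, for which the chance rate does not hold, so the excess cannot be judged. In contralateral cortex at 4 h array 11 was highest for Myc (7.94 log2 signal) and Itih4 (8.75), with the other arrays at the floor of 7.54, and in ipsilateral cortex at 24 h array 36 was highest for Matk (12.6). In ipsilateral hippocampus array 22 was highest for P2ry4 (9.64), Cp (8.08) and Slc6a11 (11.2) and lowest for Igf2r (10) and Slc16a1 (10.2). Array 18 was lowest for Hspb1 (10.3), array 17 highest for Icam2 (8.22) and array 20 lowest for Bcl2l11 (9.01). In contralateral hippocampus array 31 was highest for Zbtb24 (9.78) and Arl2 (9.7), array 28 highest for Crem (8.44) and lowest for Gabbr1 (7.54) and Aldh1a2 (7.54). Array 30 was highest for Pdgfb (8.08) and lowest for Lct (8.7), and array 32 highest for Kcnd3 (11.1).

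The side difference at 4 h differed between hippocampus and cortex for 314 probe sets by a limma test of the difference itself, with the intensity difference above entering it. In log2 units, hippocampus minus cortex, it was larger for Cited2 (2.16), the calcium channel Itpr1 (1.93), the synaptic adhesion gene Nlgn2 (1.79), Dnaja3 (1.64), Gnal (1.61) and Crem (1.49). Smaller positive values were those of the neuronal genes Gabbr1 (1.35), Homer1 (1.09), Kcna1 (1.08), Grin2c (0.845), Kcnd3 (0.838), Nptx1 (0.652), Nefl (0.599) and Pvalb (0.518), and of the lactate transporter Slc16a1 (0.705). It was lower for Foxe3 (−2.32), Afm (−2.24), Grk4 (−2.22), Cngb1 (−2.22), Ly6c (−1.87), Cebpd (−1.43), Igf2 (−1.37) and Icam1 (−1.36). Further negative values were those of Hspb1 (−1.18), Lck (−1.17), Ccnd1 (−1.12), Cp (−1.10), Bcl2l11 (−0.97), Slc1a2 (−0.836), Sod1 (−0.744), Bak1 (−0.555) and Ccnd3 (−0.378). Among list members, the probe set with the highest mean did not pass for Crem, Gabbr1, Homer1, Kcna1, Grin2c, Nefl and Slc16a1. The same held for Igf2, Ccnd1, Cp, Slc1a2 and Sod1. Of the lists, the side difference of cytokines (camera adjusted p = 0.0367), neuronal and synaptic genes (0.038) and oligodendrocyte genes (0.029) differed between the regions. Between 24 h and 4 h in cortex it differed for cytokines (0.00134), microglia (0.00519), oligodendrocyte genes (0.00519) and cholesterol synthesis genes (0.0082). None of these 7 list calls held with an estimated correlation.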

How the results depend on the processing

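The 10th percentile of signal as a covariate, alone or with an estimated correlation, bright probe sets alone and contralateral cortex at 24 h in the region comparison were chosen after seeing the data; the other alternatives were planned. No paired analysis was made, because the labels do not say which ipsilateral and contralateral samples, if any, share an animal. Any variation shared between such samples stays in the error of the side comparisons. The counts of the 2 time comparisons and of the region comparison stayed within 1.5 times of the reported ones under all alternatives but those given here. For the counts that changed the cause was not tested, except that fewer probe sets or arrays entered with bright probe sets alone and with only the arrays of the groups compared.

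In cortex at 4 h the side comparison, with 0 calls, gave 1 with quantile normalization, 5 with a lower floor, 3 with an offset in place of the floor and 2 with the 10th percentile as a covariate. In cortex at 24 h the 8 calls became 0 without the filter on dim probe sets, 0 with the arrays of the compared groups alone, 38 with array weights (8 shared), 13 with the 10th percentile as a covariate (8 shared) and 5 of the 8 with bright probe sets alone. In hippocampus the 1207 calls became 1881 with array weights (1196 shared), 5 with the 10th percentile as a covariate and 687 with bright probe sets alone (657 shared). With the Gapdh ratio as a covariate the time comparison gave 737 on the ipsilateral side (695 shared) and 601 on the contralateral side (555 shared). The change of the cortical side difference with time gave 1 with a lower floor. The difference between regions in the side difference gave 64 with the arrays of the compared groups alone (61 shared), 1 with the 10th percentile as a covariate and 188 with bright probe sets alone (178 shared). Hippocampus against contralateral cortex at 24 h gave 1483, of which 846 were shared in direction with the comparison at 4 h and 38 were opposite.

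Leaving out each array in turn gave 0 to 2 calls in cortex at 4 h, 0 to 26 in cortex at 24 h and 799 to 1446 in hippocampus. The time comparisons gave 1290 to 1565 and 1415 to 1640, the change of the side difference with time 0 to 0, its difference between regions 135 to 508 and the region comparison 2270 to 2650. In cortex at 4 h the count was 2 without array 1 and 1 without array 3, 4, 6, 8 or 15. In cortex at 24 h it was 26 without array 33, 16 without 36, 13 without 47, 3 without 41, and 0 without ipsilateral array 37, 38, 39 or 40 or contralateral array 42, 43, 44, 45, 46 or 48. In hippocampus it was 799 without array 21. The difference between regions in the side difference had 135 without array 5, 139 without 6, 151 without 18, 165 without 10, 177 without 15, 186 without 21, 190 without 16, 192 without 19, 195 without 28, 204 without 3, 487 without 8, 501 without 7 and 508 without 14.

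Of 292 values of named genes, 282 kept their direction and side of the threshold with an offset in place of the floor, 287 with array weights, 271 with a lower floor, 263 without the filter, 247 with quantile normalization, 238 with the compared groups alone, 207 with the Gapdh ratio and 172 with the 10th percentile as a covariate. With the last, 1 of 80 was kept in hippocampus and 1 of 32 in the difference between regions in the side difference, against 52 of 53 in the contralateral and 48 of 53 in the ipsilateral time comparison and 56 of 59 between regions. Against contralateral cortex at 24 h 34 of 59 were kept and 21 no longer passed. A direction turned only for Il1r2 in hippocampus (0.035 with the 10th percentile as a covariate) and, against contralateral cortex at 24 h, for Hspa5 (−0.70), Kcnj10 (−0.30), Cat (−0.16) and Idi1 (−0.046); the cause was not tested.

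Of the list calls, in cortex at 4 h the leukocyte markers were lost with the 10th percentile as a covariate (0.0602), and in cortex at 24 h cholesterol synthesis was lost with the Gapdh ratio (0.0539). For the difference between regions in the side difference the adjusted p of the cytokine list was 0.107 with quantile normalization, 0.0638 with the Gapdh ratio and 0.363 with the 10th percentile. With quantile normalization and the 10th percentile it was 0.294 and 0.303 for neuronal genes and 0.116 and 0.354 for oligodendrocyte genes. In the region comparison hippocampus-enriched markers had 0.057 with quantile normalization. Between 19.7% and 28.9% of values per array lay at or under the floor, which makes differences of such dim transcripts smaller than in the unfloored signal. In hippocampus this share itself differed by side (26.1 ± 0.89% ipsilateral, 22.9 ± 1.7% contralateral, SD). Differences of dim transcripts there may therefore also come from the intensity difference between the arrays, which was not told apart.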

Other observations

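The tests of the ribosomal protein genes were prompted by the Rpl21 call in the same arrays and chosen before their own results were seen. The 10th percentile of signal as a covariate, 1 of the alternatives used, was chosen after.

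With 1 ribosomal protein gene, Rpl21, among the 5 named genes of cortex at 24 h, it was tested whether ribosomal protein genes may shift as a set on the ipsilateral side. Of 44 measured, 37 were higher by a median of 0.171 log2 units (camera p = 0.000234 with an estimated correlation, 5.72e-18 with the preset one), while 0 passed alone by the probe set with the highest mean. A shift of bright probe sets in general is argued against, since 1000 random lists matched on mean expression had a 95th percentile of 0.0203 and 0 were as high as 0.171. With each array left out in turn the p with an estimated correlation ran from 7.22e-05 to 0.000756 and the median from 0.143 to 0.187, and under 5 alternative settings the p ran from 0.00015 to 0.000581. In cortex at 4 h 24 of 44 were higher (p = 0.757 with an estimated correlation) and in hippocampus 26 of 44 (p = 0.264). Whether the source is dividing or infiltrating cells was not tested.

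The mean of the microglia and macrophage markers on single ipsilateral cortex arrays at 24 h was −0.0798 on array 33, −0.0823 on array 34, 0.0559 on array 35, 0.0413 on array 36, 0.733 on array 37, 1.03 on array 38, 0.728 on array 39 and 0.697 on array 40. Contralateral arrays lay between −0.242 and 0.0933. Pooled over the 3 side comparisons, the ipsilateral variance over the contralateral one was 6.84 for microglia and macrophage markers and 4.58 for reactive astrocyte genes. The labels do not say whether these arrays differ in treatment, and whether both sham-operated and injured animals are among them was not tested.

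Transthyretin, Ttr, a product of the choroid plexus, varied widely within every group. It ran from 10.1 to 16.4 log2 signal on the ipsilateral side of hippocampus and from 10.3 to 16.3 on the contralateral side (13.24 ± 2.7 against 13.65 ± 2.8, SD, n = 7 and 9). In cortex at 4 h it ran from 9.19 to 15.9 and from 10.2 to 15.6, and at 24 h from 9.62 to 15.1 and from 9.28 to 15.6. In none of the 3 side comparisons did it pass.

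The first principal component over the tested probe sets held 16% of the variance, the second 12.8% and the third 8.94%.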
